A study of Mus musculus with 6 samples.

How the data were processed

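Total RNA from 2 kinds of sorted, cultured mouse CD8+ T cells was hybridised to 3 array types, 1 array per kind and type, per the labels. The samples were grouped by their titles as central memory (CM) or effector/effector memory (E/EM) cells on SubA, SubB or SubC. The deposited values are linear probe set intensities, 1 table per array type. What the authors did to make them is not given in the sources used here beyond the values themselves. The deposited intensities have a mean, after leaving out the lowest and highest 2% of each array, that lies close to 500 on each array (from 500.1 to 500.3), as in arrays scaled to a common target. The arrays of a table differed in that mean by at most 0.00858%, under the 5% limit set in advance, so the values were used as deposited with no further normalization. The array maker's software, its version and any detection calls are not given in the sources used here.

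The tables held 12488, 12477 and 11934 probe sets on SubA, SubB and SubC, of which 66 on each were control probe sets shared by all 3. Gene symbols came from GEO's platform annotation. A single symbol was given for 10855, 10603 and 7739 probe sets, several symbols for 396, 178 and 150, and none for 1237, 1696 and 4045. Symbols were checked by Entrez gene identifier against a RefSeq table of assembly GRCm38.p6, which held 10839, 10572 and 7699 of them and changed 0. No genome build is named for the probe sets, so no coordinates are given. Probe sets with several symbols or none named no gene.

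The floor of a table was the higher of its 2 arrays' 90th percentiles over 15 probe sets for bacterial poly-A controls, whose median lay under that of all probe sets. It was 31.28 on SubA, 88.12 on SubB and 194.34 on SubC. The share of probe sets above it was 66.9% (CM) and 69.1% (E/EM) on SubA, 64.3% and 68.7% on SubB, and 47.0% and 47.2% on SubC, so SubC measured fewer genes and weaker ones with less precision. The 3'/5' signal ratio of the actin control, a measure of RNA integrity, was between 1.06 and 1.17 on the 6 arrays, and that of the Gapdh control between 0.794 and 0.903. The number of arrays limits the precision of every value.

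A probe set above the floor on both arrays gave a log2 ratio of CM over E/EM signal. A gene's value was the mean of these ratios over its probe sets and array types, with the SD over probe sets. The median of that SD over 4094 genes with at least 2 such probe sets was 0.321, against 0.364 for 2 probe sets drawn at random. A gene above the floor in 1 kind of cell only was given as at least N-fold, the signal over the floor, and was not ranked. Of 15964 named genes, 10946 had a ratio, 1583 had a bound only and 3435 had neither. With 1 array per group there was no test and no p-value, and genes were counted by a rule of size, 2-fold.

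The position of a gene list was the percentile of its median log2 ratio among 10000 random lists of the same size, matched on mean log2 signal in 20 bins, for lists with at least 5 measured members. The outer 5% lies below percentile 2.5 or above 97.5. The 26 lists, the 10 alternatives, the floor and the rule for naming genes were fixed before the data were examined. The lists covered naive and central memory genes, cytotoxic effector genes, effector and activation genes, cytokines, chemokine receptors and integrins, IL-2 and IL-15 receptor and STAT5 genes, cell cycle, glycolysis, fatty acid oxidation, oxidative phosphorylation, cholesterol synthesis, amino acid transport and synthesis, apoptosis, interferon-stimulated, ribosomal protein, immediate early, endoplasmic reticulum stress, natural killer receptor and T cell identity genes. The rest were markers of B cells, helper T cells, macrophages, monocytes and neutrophils, dendritic cells, erythroid cells, stromal and endothelial cells, and mast cells and basophils. The 3 second lists of the closing section were written after the results of the fixed lists were seen and before their own values were computed.

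The rule for named genes took Il2ra, Il2rb, Il2rg, Il15ra, Cd8a, Cd44 and a further gene that is not reported here. To these it added the 8 highest and 8 lowest genes whose probe sets were all at least 2 times the floor on both arrays and of the same sign, leaving out immunoglobulin and T cell receptor variable segments. It also took the 3 largest bounds in each direction, up to 4 members of each list with the largest ratio in size, and list members with a bound of at least 4-fold. Genes named outside the rule are said to have been singled out after their values were seen.

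The alternatives were quantile normalization within a table, centring each table's ratios on their median, the floor halved, doubled or set at the 60th percentile of all probe sets, the brightest probe set per gene, leaving out probe sets marked as shared, SubA alone, a 3-fold rule, and random lists matched on size only. SubA with SubB but without SubC was added after the data were seen. The calculations were tested on simulated data built from the real signals, with noise of the observed spread. Over 11918 genes, planted log2 ratios of 2, -2, 1.5 and -1.5 were recovered with medians of 1.98, -2.02, 1.49 and -1.71, and 97.9%, 98.0%, 87.5% and 93.9% passed 2-fold in the planted direction. Of 200 simulated lists of 20 genes without a shift 4% fell in the outer 5%, and 97% of lists shifted by -0.4 were found. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.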

Results

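Gene expression was measured in 2 kinds of CD8+ T cells grown in culture from female P14 mice on the C57Bl/6 background. P14 mice carry a transgenic T cell receptor that recognises a peptide of the lymphocytic choriomeningitis virus glycoprotein. Spleen and lymph node cells received their peptide for 2 days and a cytokine for the next 7 days. Cells kept in IL-15 were called central memory cells and cells kept in IL-2 effector/effector memory cells, and each kind was sorted for high or low levels, respectively, of a surface marker. Each kind was hybridised to 3 array types, named SubA, SubB and SubC, which carry different probe sets, so the 6 arrays gave 1 array per kind and array type. There were no replicates, and the labels do not say whether the 3 arrays of a kind carried the same RNA. The values below therefore describe these arrays, and no p-value was computed. The spread given with a gene is the standard deviation (SD) over its probe sets, which is technical, and a gene without a spread was measured by 1 probe set. All ratios are central memory over effector/effector memory signal on the log2 scale, so a negative value means a lower signal in central memory cells. A ratio is less certain in size where the weaker signal was under 2 times the floor, which is stated for some genes only.

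The comparison asked how the transcripts of IL-15 central memory cells and IL-2 effector/effector memory cells differ. The granzymes Gzmc, Gzmd and Gzma, proteases of cytotoxic granules, had the lowest log2 ratios of all measured genes, -5.98, -5.82 and -5.34. Prf1, which encodes the pore-forming protein perforin, had -3.47. At the other end, Nsg2 had a log2 ratio of 3.89, Dapl1 2.98 and Samd3 2.89. The value of Dapl1 rests on 1 SubC probe set, and 2 SubB probe sets above the floor in central memory cells alone put its log2 ratio at 5.73 or more and 4.72 or more. With the floor halved, which brings these in, Dapl1 had 4.74. Klf2, a transcription factor of resting T cells that maintains S1pr1 expression, had 2.02. Among 10946 named genes measured above the floor in both kinds of cells, 614 (5.61%) were at least 2-fold lower in central memory cells and 299 (2.73%) at least 2-fold higher. The 4-fold rule gave 81 lower and 25 higher genes. A further 263 genes lay at or under the floor in central memory cells alone and were at least 2-fold lower there, and 105 were bounded in the opposite direction. The median log2 ratio of all measured genes was -0.0025. In simulated arrays with noise of the observed probe set spread, 3.34% of unchanged genes passed 2-fold, both directions counted together. The observed spread includes any real differences between the cells and was held equal over signal strengths, so 3.34% is not a pure noise rate. Part of both counts can be noise, but how much is not known.

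**Figure D1:**
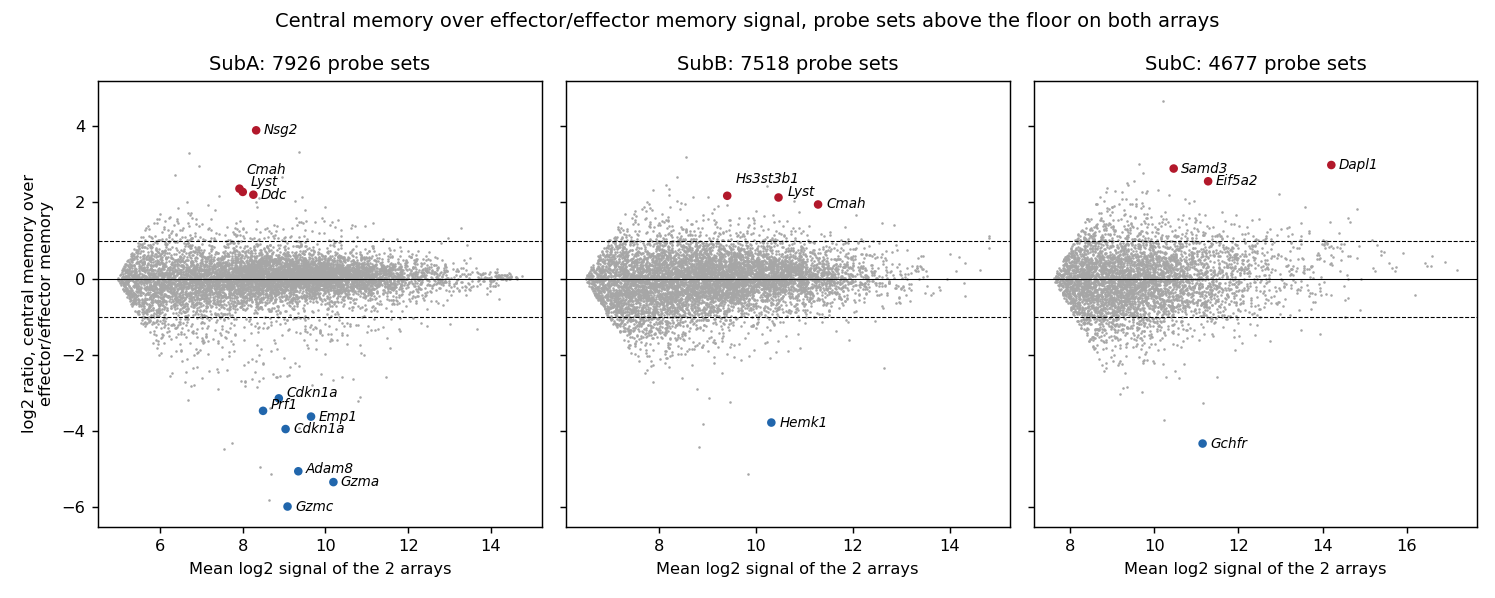
Each point is a probe set above the floor on both arrays of a table, with the mean log2 signal of the 2 arrays on the horizontal axis and the log2 ratio of central memory over effector/effector memory signal on the vertical axis, for SubA (7926 probe sets), SubB (7518) and SubC (4677). Coloured points are the genes with the highest (red) and lowest (blue) ratios among genes at least 2 times the floor, dashed lines mark 2-fold, and the scatter widened from SubA to SubC, with a robust SD of 0.38, 0.54 and 0.69.

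Apart from the granzymes and perforin, the lowest ratios among genes at least 2 times the floor on both arrays belonged to Adam8, a cell surface metalloprotease, at -5.06 with a signal of 112.7 against 3752. Gchfr, which encodes the feedback regulator of GTP cyclohydrolase I, had -4.33, Hemk1 had -3.78 and Emp1 had -3.62. Cdkn1a, the cyclin-dependent kinase inhibitor p21, had -3.55 ± 0.57 (SD, 2 probe sets). The largest bounds in the same direction were for Gzmg, at least 33.5-fold lower in central memory cells, for Esm1, at least 19.9-fold lower, and for Cdkn2b, another cyclin-dependent kinase inhibitor, at least 17.8-fold lower. Granzymes C to G are near-identical copies, so their probe sets may share signal and each of these values is uncertain for the individual gene.

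By the same limit, the genes highest in central memory cells besides Nsg2, Dapl1 and Samd3 included Eif5a2 at 2.56, a translation factor paralogue. Lyst, a regulator of lysosome and granule size, had 2.20 ± 0.10 (SD, 2 probe sets on 2 array types). Ddc, the aromatic amino acid decarboxylase, had 2.20, Hs3st3b1, a heparan sulfate sulfotransferase, had 2.18, and Cmah had 2.16 ± 0.29 (SD, 2 probe sets). Dyrk4 was at least 16.5-fold higher, Il6ra, the IL-6 receptor alpha chain, at least 10.9-fold higher, and Btbd11 at least 7.76-fold higher.

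Il2ra, the high-affinity IL-2 receptor alpha chain, had the largest difference among the measured chains of the IL-2 and IL-15 receptors, with a log2 ratio of -2.52 and signals of 234.2 in central memory and 1340.7 in effector/effector memory cells. The shared beta chain Il2rb had -0.41 ± 0.06 (SD, 2 probe sets), and the IL-15 receptor alpha chain Il15ra had 0.19. Cd8a had 0.20 and the memory and activation marker Cd44 had -0.31 ± 0.27 (SD, 3 probe sets). Il2rg, the common gamma chain, was not named on these arrays. Over the 18 measured IL-2 and IL-15 receptor chains and STAT5 targets the median was -0.02, at percentile 27.9 of random lists matched on signal. Only Il2ra and Cish, a suppressor of cytokine signalling with -1.07, were at least 2-fold lower in that list. Pim2 had -0.69 ± 0.16 (SD, 2 probe sets), whereas Socs3 had 0.80 ± 0.09 (SD, 3 probe sets).

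Naive and central memory T cell genes were higher as a group in central memory cells. Of 18 measured members 6 were at least 2-fold higher and 0 at least 2-fold lower, with 15 above 0, and their median of 0.57 lay at percentile 100, above the 95% range of random lists, -0.21 to 0.27. Besides Dapl1 and Klf2, the costimulatory receptor Cd27 had 1.74 ± 0.41 (SD, 2 probe sets) and Klf3 1.74 ± 0.88 (SD, 3 probe sets). The lymph node homing receptor Ccr7 had 1.58. S1pr1, the receptor for exit from lymphoid organs, had 1.56, with a weaker signal only 1.59 times the floor. Both genes were singled out after their values were seen. So were the 3 members below 0, Id3 at -0.73, the IL-7 receptor gene Il7r at -0.45 and Ltb at -0.10. The T cell receptor and identity genes also lay high, with a median of 0.34 at percentile 99.5 over 19 members, 12 above 0 and 7 below. The chains of the receptor complex, singled out after their values were seen, were not raised together. Cd3g had -0.72 and Cd247 0.34, and the probe sets of Cd3e and Cd3d lay between -0.12 and 0.06. In that list Cd6 had 1.44 ± 0.06 (SD, 2 probe sets), Cd5, a negative regulator of receptor signalling, had 1.13, and Gata3 had 0.77 ± 0.07 (SD, 3 probe sets). Runx3, a transcription factor of cytotoxic T cells, went the opposite way, 2.83-fold lower with signals of 111.8 against 316.9, and was the only member at least 2-fold lower. Its weaker signal was only 1.27 times the floor.

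Effector and activation regulators and surface receptors were lower in central memory cells. Of 15 measured members 9 were at least 2-fold lower and 0 at least 2-fold higher, and their median of -1.35 lay at percentile 0, below all 10000 random lists. The inhibitory receptors Pdcd1 and Lag3 had -2.71 and -2.62, the costimulatory receptor Tnfrsf4 (OX40) had -1.85, and the transcription factor Irf4 had -1.60. The central memory signal of Pdcd1 was only 1.22 times the floor. Ctla4 at -1.49 and Prdm1, which encodes Blimp-1, at -1.36 were singled out after their values were seen. The cytotoxic effector genes were split. Of 15 measured members 6 were at least 2-fold lower and 1 at least 2-fold higher. Their median of -0.30 lay at percentile 1.08, their mean was -1.38, and with 3 bounded members added the median was -0.90. Gzmf was at least 4.89-fold lower. Gzmb and Gzmm were singled out after their values were seen. Gzmb was abundant in both kinds of cells, with signals of 8145.7 and 20413.3 and a log2 ratio of -1.33, while Gzmm was 3.04-fold higher in central memory cells (log2 SD 0.38, 2 probe sets). The position of the cytotoxic list was lost with the floor at the 60th percentile of all probe sets (percentile 6.56) and without probe sets marked as shared between genes (percentile 2.95).

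**Figure D2:**
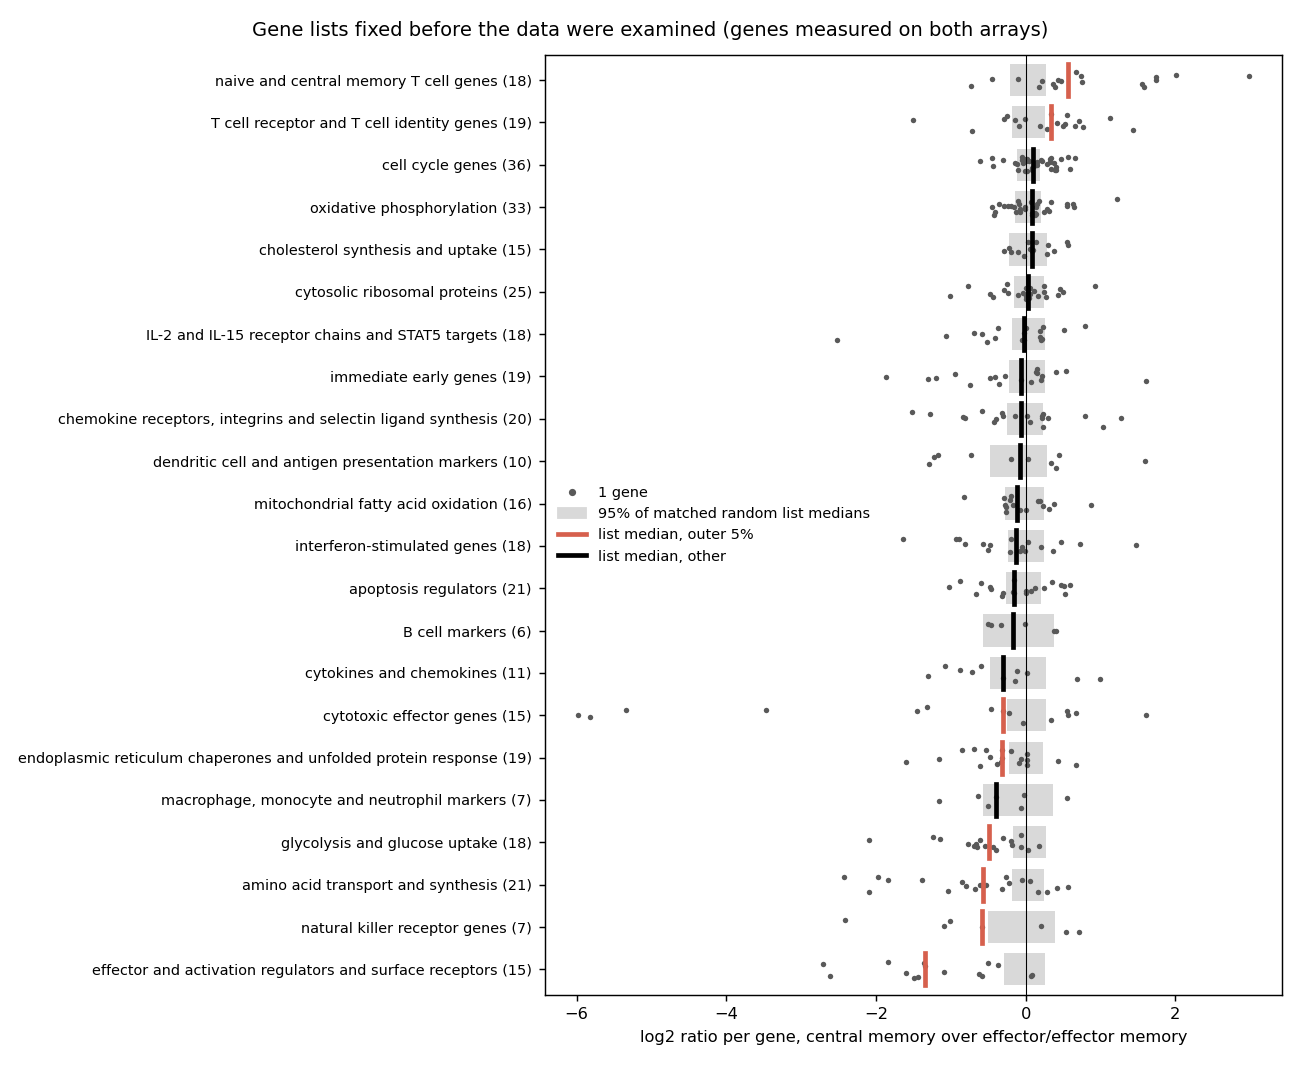
Each grey point is the log2 ratio of 1 gene, central memory over effector/effector memory, in the gene lists fixed before the data were examined, with the number of measured genes in parentheses. Vertical bars are list medians, red where they lie in the outer 5% of 10000 random lists matched on signal, and grey bands hold 95% of the random medians. The medians run from 0.57 for naive and central memory genes to -1.35 for effector and activation genes.

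Genes of glycolysis and glucose uptake were lower in central memory cells. Of 18 measured members 16 had a negative log2 ratio, 3 were at least 2-fold lower and 0 at least 2-fold higher, and the median of -0.49 lay at percentile 0, against -0.16 to 0.27 for random lists. The glucose transporter Slc2a3 had -2.09 ± 0.47 (SD, 3 probe sets), hexokinase Hk2 -1.23, the lactate exporter Slc16a3 -1.15 and the glucose transporter Slc2a1 -0.77. Genes of mitochondrial fatty acid oxidation showed no such position, with a median of -0.12 at percentile 17.97 and 0 of 16 members past 2-fold. Acadm and Acadl, both acyl-CoA dehydrogenases, had 0.88 and -0.83, Acaa2 had 0.37 and Echs1 0.31. Oxidative phosphorylation genes had a median of 0.08 at percentile 74.2 over 33 members. Ndufs4 was the only member past 2-fold, at 1.22 ± 0.28 (SD, 2 probe sets), followed by Ndufs1 at 0.65 ± 0.35 (SD, 3 probe sets), Ndufs8 at 0.63 and Cox7a2 at 0.55 ± 0.66 (SD, 2 probe sets). Quantile normalization brought Ndufs8 to 0.28. Cholesterol synthesis and uptake genes had a median of 0.08 at percentile 63.6, with Mvk at 0.57 ± 0.14, Idi1 at 0.56 ± 0.05 and Fdps at 0.37 ± 0.05 (SD, 2 probe sets each) and Sqle at 0.30.

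The amino acid transport and synthesis list, which also holds Atf4, stress response genes and aminoacyl-tRNA synthetases, was lower in central memory cells. Of 21 measured members 6 were at least 2-fold lower and 0 at least 2-fold higher, with a median of -0.57 at percentile 0.01. Below 0 were 16 members and above it 5, among them the serine synthesis genes Phgdh at 0.16 and Psph at 0.28. These 2 genes were singled out after their values were seen. The stress response genes Sesn2, Trib3, Chac1 and Ddit3, which belong to that list as targets of the transcription factor ATF4, had -2.43, -2.09, -1.97 and -1.84. The neutral amino acid transporter Slc1a4 was at least 8.50-fold lower. Endoplasmic reticulum chaperones and unfolded protein response genes had a median of -0.32 at percentile 0.36, with 2 of 19 members at least 2-fold lower. Xbp1, the transcription factor of that response, had -1.60, Sdf2l1 -1.16, Hyou1 -0.85 and Pdia3 -0.69.

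Cytokine and chemokine genes were mixed. Il10 was at least 11.6-fold lower in central memory cells. The chemokines Ccl4 and Ccl3 had -1.30 and -0.88, and Ccl5 had 0.99. The 2 probe sets of Lta disagreed, so its mean of -1.08 ± 2.15 has no settled direction. The list median of -0.30 lay at percentile 12.8 over 11 members, but at 2.02 after quantile normalization and at 0.56 with the floor doubled. Chemokine receptor, integrin and selectin ligand genes had a median of -0.06 at percentile 31.7 over 20 members. Cxcr3, a receptor for interferon-induced chemokines, had 1.27 and St3gal6 1.03 ± 0.51 (SD, 3 probe sets), whereas the integrin chain Itgav had -1.52 ± 0.29 and Gcnt1 -1.28 ± 0.88 (SD, 2 probe sets each). Gcnt1 was at -0.65 with the floor doubled and on SubA alone.

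Natural killer receptor genes had a median of -0.58 at percentile 1.22 over 7 members, which became -0.20 with bounded members added, and -0.15 at percentile 35.6 with the floor halved. The percentile after quantile normalization was 3.72. Cd244a had -2.41, Klrk1 (NKG2D) -1.09 ± 0.52 (SD, 3 probe sets) and Cd160 -1.01, and Klrd1 (CD94) had 0.72. Klrk1 was under 2-fold in several alternatives, with -0.50 at a doubled floor, and Cd160 had -0.15 with the floor halved. Immediate early genes had a median of -0.06 at percentile 24.6 over 19 members. Gadd45b had -1.87, Ier3 -1.31 and Egr3 -1.19, and Fosb was 3.04-fold higher, with signals of 1081.6 against 356.1. The weaker signal of Egr3 was only 1.09 times the floor. Ier3 had -0.94 with the floor halved. That list moved to percentile 0.455 with the brightest probe set per gene and to 0.33 without shared probe sets. Interferon-stimulated genes had a median of -0.13 at percentile 11.2 over 18 members, with Mx1 at -1.64, Gbp3 at -0.93, Iigp1 at -0.89 ± 0.10 (SD, 2 probe sets) and Ifit2 at 1.47.

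Cell cycle genes differed little between the kinds of cells. None of 36 measured members passed 2-fold, and the median of 0.10 lay at percentile 79.6. The largest values were 0.66 for Kif11, -0.62 ± 0.11 (SD, 2 probe sets) for Cdc45, 0.60 for Ccna2 and 0.56 for Stmn1. Cytosolic ribosomal protein genes had a median of 0.03 at percentile 50.4 over 25 members and a mean of -0.0030. Rplp2 had -1.01, Rps6 0.92, Rps13 0.49 ± 0.23 (SD, 2 probe sets) and Rps3 -0.77 ± 0.77 (SD, 3 probe sets), and Rpl13 was at least 5.02-fold lower. The weaker signal of Rps6 was only 1.004 times the floor. The brightest probe set of Rps3 had 0.09, and Rplp2 fell under 2-fold, to -0.98, with each table centred on its median. Apoptosis regulators had a median of -0.15 at percentile 12.7 over 21 members, with Birc3 at -1.02, Pmaip1 (Noxa) at -0.88, Casp1 at -0.66 and Apaf1 at -0.60. Birc3 had -0.01 with the floor halved.

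Many markers of other cell types lay at or under the floor, but not all. Ighm and H2-DMa were singled out after their values were seen. The brightest probe set of the B cell marker Ighm had signals of 5306.6 in central memory and 3802.4 in effector/effector memory cells. Another Ighm probe set had signals of 3311.8 and 2711.3, and most of the rest lay at or under the floor. The brightest probe set of the antigen presentation gene H2-DMa had signals of 2055.2 and 1225.4. B cell markers had a median of -0.16 at percentile 34.1 over 6 members, with Cd79a at -0.51, Ms4a1 at -0.47, Blk at 0.41 and Cd79b at 0.39. Macrophage, monocyte and neutrophil markers had -0.39 at percentile 10.985 over 7 members, with Cd68 at -1.16, Cd14 at -0.63, Ctss at 0.55 and Csf3r at -0.50. Dendritic cell and antigen presentation markers had -0.08 at percentile 50.3 over 10 members. The class II genes H2-Ab1, H2-Eb1 and H2-DMb1 had -1.29, -1.23 and -1.17, and Itgax (CD11c) was 3.02-fold higher with signals of 130.3 against 43.1. On SubA alone the median of the dendritic cell list was -0.46 at percentile 1.88. The helper T cell marker Cd4 had 1.42, with signals of 131.7 in central memory and 49.3 in effector/effector memory cells, and Zbtb7b was at least 9.74-fold lower.

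Fewer than 5 genes were measured in each of the remaining lists, so no percentile was computed for them or for the helper T cell markers. Of mast cell and basophil markers, Kit had -1.86 with signals of 48.1 against 174.9, Ms4a2 -0.99 and Tpsb2 -0.65 ± 0.45 (SD, 2 probe sets). Among erythroid markers Epor had 0.74, Klf1 -0.50, Hba-a1 0.49 and Slc4a1 -0.33 ± 1.06 (SD, 2 probe sets). The probe sets of Slc4a1 disagreed, with 0.42 on SubA and -1.08 on SubC, so its mean has no settled direction. The stromal and endothelial markers Pecam1, Pdgfra, Col1a1 and Col1a2 had 0.46, 0.42, -0.38 and -0.19.

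Of the 22 lists with a percentile, 8 lay in the outer 5% of random lists, against 1.1 for lists of genes drawn at random. Genes of a list can vary together, and some lists were written for these kinds of cells. The 1.1 is thus not the number expected by chance for such lists. Genes measured on more than 1 array type gave the nearest thing to a repeat. Of 61 genes at least 2-fold apart on SubA and also measured on SubB, 56 (91.8%) had the same sign there and 23 (37.7%) were again past 2-fold. The corresponding counts were 38 of 46 genes (82.6%) for SubA and SubC and 57 of 81 genes (70.4%) for SubB and SubC, and 15 of the 46 (32.6%) and 17 of the 81 (21.0%) were again past 2-fold. Across the 1247 genes shared by SubA and SubB the log2 ratios correlated with Pearson r = 0.46 and Spearman rho = 0.40, where genes are not independent replicates. The r was 0.26 for SubA and SubC and 0.22 for SubB and SubC.

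**Figure D3:**
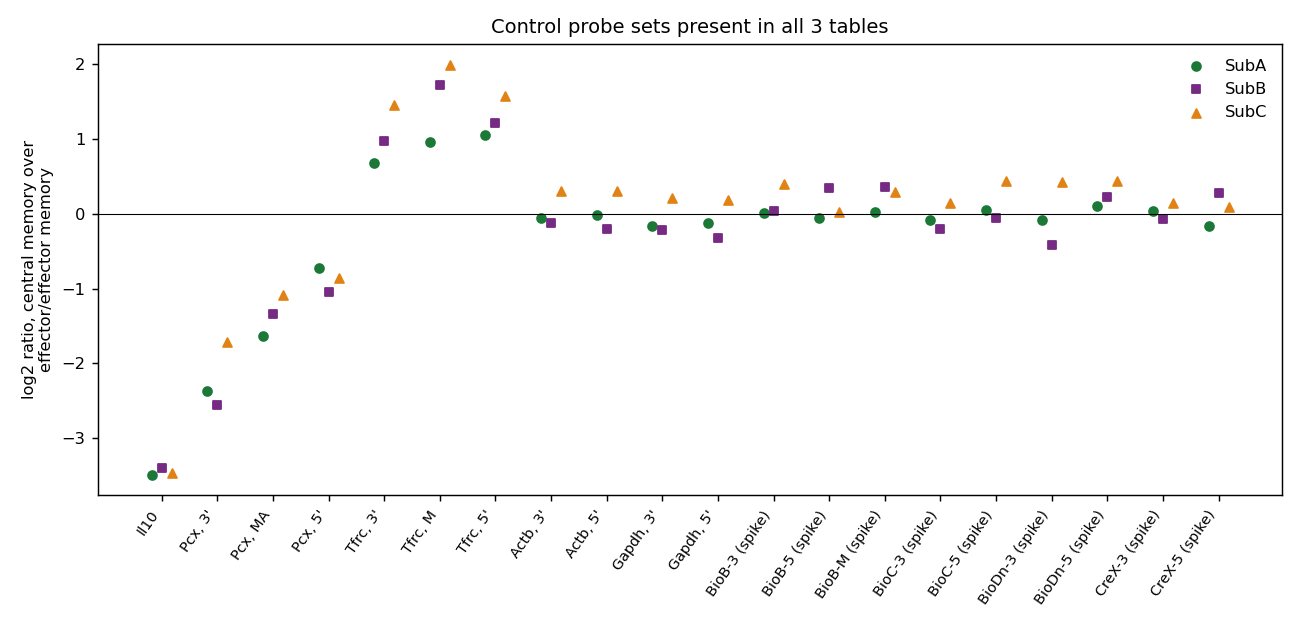
Log2 ratio of central memory over effector/effector memory signal for control probe sets present on all 3 array types, with 1 point per array type (for Il10 on SubA and SubC a limit set by the floor). Il10 and Pcx lay below 0 and Tfrc above 0 on SubA, SubB and SubC, while Actb, Gapdh and the bacterial hybridisation spikes lay nearer 0. The spikes had a mean of 0.10 and an SD of 0.219 over 27 values, with means of -0.02, 0.05 and 0.27 on SubA, SubB and SubC. On SubC the Actb and Gapdh values shown, 0.18 to 0.31, were shifted the same way.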

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

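The limit used in this part was not among the choices fixed before the data were examined. Besides gene probe sets, the arrays carry control probe sets for mouse transcripts that the comparisons above left out. Of 23 such probe sets 10 had a log2 ratio of the same sign and beyond 0.657 in size on each of the 3 array types, where 0.657 is 3 SD of the hybridisation spikes. The values below are means over the array types. Control probe sets above the floor on all 6 arrays had a median SD of 0.240 over the array types.

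The control probe set for Il10, an anti-inflammatory cytokine, had a mean of -3.45. Its central memory signal lay under the floor on SubA and SubC and at 90.2 against a floor of 88.12 on SubB, so the mean is a limit set by the floor. The control probe sets for the transferrin receptor Tfrc, which brings iron into dividing cells, had 1.04 at the 3' end, 1.56 in the middle and 1.28 at the 5' end, higher in central memory cells. The 4 gene probe sets of Tfrc had 0.65 ± 0.28 (SD). The control probe sets for pyruvate carboxylase, Pcx, an enzyme that refills the citric acid cycle, had -2.21 at the 3' end, -1.35 and -2.20 in the middle and -0.88 at the 5' end. The -2.20 includes a limit on SubA, where the central memory signal of that probe set lay under the floor, so it is a limit as well. The gene probe set of Pcx above the floor had -0.18 at 2.18 times the floor, and the gene had -1.54 with the floor halved. The control probe set for the 5' end of 18S ribosomal RNA had -1.05 and the murine B1 repeat control had -0.85. The values of the Tfrc and Pcx gene probe sets were singled out after they were seen.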

How the results depend on the processing

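The alternative without SubC was chosen after the data were seen. No paired analysis was possible because each kind of cell had 1 array per array type, and leaving out a replicate was not possible for the same reason. The excess of genes lower in central memory cells held in every alternative, from 1.48 times the higher genes with the floor at the 60th percentile to 2.77 times under the 3-fold rule. The counts of higher and lower genes moved by over 1.5 times with the floor halved (480 and 948), with the floor at the 60th percentile (184 and 273), on SubA alone (123 and 256) and under the 3-fold rule (61 and 169). With the floor doubled the lower count moved, to 385. These follow from measuring more or fewer genes or from a stricter rule. Of 213 comparisons of a list median with its main value, 22 changed only the random lists and so could not move the median. In all, 207 of the 213 stayed within the spread between probe sets of a gene, a change under 0.321. The others were natural killer receptors with the floor halved (-0.15), cytokines with the floor doubled (-0.71), dendritic cell markers at -0.46 with the floor doubled, on SubA alone and without SubC, and effector and activation genes with the floor at the 60th percentile (-0.83, still at percentile 0). More or fewer members were measured in these lists under those settings. The limit of 0.321 is loose for a list, since many list medians were smaller than that in size. A list within it can still change position. Immediate early genes went from -0.06 at percentile 24.6 to -0.35 at percentile 0.33 without shared probe sets. The naive and central memory, effector and activation, glycolysis, amino acid, endoplasmic reticulum and T cell identity lists stayed in the outer 5% in every alternative. Of 79 genes named in the text at 2-fold or more with a ratio, 7 were under 2-fold in at least 1 alternative that still gave a ratio. Lta reversed to 0.44 without shared probe sets, which leaves its other probe set alone. Of 1141 comparisons of a named gene with its main value, 1115 stayed within the spread. A gene with 1 probe set keeps nearly the same value in most alternatives. A gene that lost its ratio in an alternative was not compared there. Both counts therefore say little about how firm the gene values are. The median SD of the control probe sets was 0.213 after quantile normalization. Signal over background limits SubC most, where the floor was 194.34.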

Other observations

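The tests of a signal-dependent difference between arrays were chosen only after the list results were seen. So were the genes named in this part. The interval rule for genes far above the floor was also set after the value was seen.

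Mt2, a metallothionein that binds zinc and copper, had a log2 ratio of -3.21 with signals of 581.1 in central memory and 5359 in effector/effector memory cells. Gpt2, a mitochondrial alanine transaminase, had -2.72, although its central memory signal was only 1.04 times the floor, Eif4ebp1, a repressor of translation initiation, -1.61, and Ddit4, an inhibitor of mTORC1, -1.55. Of 18 measured HIF1 target genes outside the glycolysis list 15 were below 0 and 6 at least 2-fold lower. Ero1a had -1.45, Ndrg1 -1.33, Bnip3 -1.23 and Vegfa -0.90. The 18 include Pfkfb3 and Pfkfb4, which regulate glycolysis, at 0.10 and -0.46. The listed p53 target genes were mixed, with 12 of 19 measured members below 0, 7 above 0 and 15 under 2-fold. Cdkn1a, at -3.55, is also a p53 target but was not in that list, so the list does not cover the whole programme. Dcxr had -1.93, Phlda3 -1.90 and Ccng1 -1.46, whereas Sesn1 had 0.71 and Xpc 0.50. Vegfa had -0.21 with the brightest probe set. Of 2995 probe sets without a single gene symbol 218 were at least 2-fold lower and 108 at least 2-fold higher in central memory cells.

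The amino acid transport and synthesis list was lower in central memory cells, and a hypothesis is that a wider ATF4 target programme differed. That fixed list itself holds Atf4 and several ATF4 targets, so only the second list bears on this hypothesis. A difference that depends only on signal strength would shift the signal-matched random lists too, and the fixed list lay at percentile 0.01 among them. This argues against such a difference where the array types share it, since the matching pooled them. Quantile normalization, done within each table, left a median of -0.55 at percentile 0, which argues against a difference particular to 1 table. SubA alone gave -0.57 at percentile 0 over 17 members. A second list of 24 measured ATF4 targets, none of them in the fixed lists, had a median of -0.40 at percentile 0.05 (0 to 0.1 over the alternatives), as the hypothesis needs. A p53 target programme is another candidate explanation for the shared stress genes. Its list of 19 measured genes, which leaves out Cdkn1a, had a median of -0.35 at percentile 0.46 (0 to 1.07). Both stay open, since ATF4 and p53 share targets such as Sesn2 and the sort, the cytokine and the array differ together between the kinds of cells.

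Glycolysis and glucose uptake genes were lower in central memory cells, and a hypothesis is that a wider HIF1 target programme differed. The list lay at percentile 0 among random lists matched on signal over all array types. This argues against a difference that depends only on signal strength and is shared by the array types. Quantile normalization within each table left a median of -0.43 at percentile 0.02, which argues against a difference particular to 1 table. SubA alone gave -0.40 at percentile 0 over 17 members. The 18 measured HIF1 targets outside the glycolysis list had a median of -0.74 and a percentile of 0. They lay below all 10000 random lists in the main setting and in every alternative. The wider HIF1 target programme may thus differ as well. All 3 second lists lay low, so these tests do not separate 1 regulator from a wider difference in activation.

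More genes were 2-fold lower than 2-fold higher in central memory cells. An offset of the median gene does not account for this, since the table medians were only 0.02, -0.01 and -0.03. After centring on them the lower genes were still 2 times the higher ones (608 and 304, 95% counting interval 1.74 to 2.30). The arrays were already scaled, so centring moved little and cannot show an offset that the scaling itself made. The hybridisation spikes had mean log2 ratios of -0.02, 0.05 and 0.27 on SubA, SubB and SubC. Quantile normalization, which also removes differences that depend on signal, left 547 lower and 362 higher genes, a ratio of 1.51, so a signal-dependent difference stays open for part of the excess. For noise of probe sets near the floor, the ratio among 5562 genes at least 4 times the floor was 1.78 (167 and 94). The rule set in advance took a ratio of 1.5 or more as arguing against such noise, and 1.78 met it. The requirement on the interval was added after the value was seen. The interval of 1.38 to 2.29 includes values under 1.5, so by that stricter requirement such noise cannot be told apart from a real excess. Counting intervals treat genes as independent, which they are not.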
